A study of Mus musculus with 6 samples.

How the data were processed

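Gene expression was measured in 6 samples of mouse bone marrow monocytes, 3 cultured in M-CSF and 3 in M-CSF with IFN-beta, on 1-colour Agilent arrays. Per the file headers, the authors scanned the arrays and extracted the spots with Agilent Feature Extraction 12.0.3.1. The deposited scanner files hold an intensity per spot (the processed signal, which the software had detrended and replaced by a surrogate for dim spots, beside the raw mean signal and the local background), with no normalization between arrays per the file headers. The deposited value table holds log2 values of the same arrays. Its processing is not stated beyond limma, which the submitters' processing notes name, so it was set against the scanner files. Each of its columns correlated with the log2 processed signal of its own array (r from 0.996 to 0.999 over 56605 probes), the column medians were 4.81, 4.81, 4.82, 4.82, 4.82 and 4.80, the quantiles of the columns were nearly equal, and the values were not centred per gene. The exact normalization of that table stays unknown, and it served only as an alternative.

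The files give 59305 non-control spots per array for 56605 probes. Spots marked as non-uniform or population outliers, 135 to 174 per array, were left out, which set aside 7 probes, and spots of 1 probe were averaged. The values analysed are log2 of the processed signal minus its 75th percentile on the array, so each level is relative to that percentile. A probe was tested if it lay well above background on every array of at least 1 group (29794 probes). A gene with several probes was represented by the probe with the highest mean over the 6 arrays, which left 19500 genes, 14482 of them with a current symbol. Of 1266 changed genes with several probes, 189 had a probe of opposite sign, and the text says where a named gene is among them.

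Symbols came from the files and from a table of RefSeq genes (assembly GRCm38.p6), which was used for names only. Of 35886 probes with a RefSeq accession, 32994 were named through it, 10224 further probes kept a symbol of the files that the table holds, and 13387 had no current symbol and kept the name in the file. Probe positions are those of the files, on mm9. No genome sequence was used, so probes were not mapped again.

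IFN-beta was compared with control in limma (3.58.1, R 4.3.3, with the package data.table, version 1.17.8) by lmFit and eBayes, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The groups were those of the labels, and no covariate was used. Errors of log2 fold changes are the fit's standard errors, on 4 residual degrees of freedom plus the prior. A gene not well above background on any array of a group was given as a bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the gene's own value and the lowest signal among probes well above background on that array. Where a named gene lay above background on only some arrays of a group, its bound was formed likewise from those arrays. No array had a saturated probe.

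Gene lists, 41 in number and 10 of them markers of other cell types, were tested with limma's camera at its preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the lists, and also with the correlation between genes estimated from the data and with fry. With an estimated correlation camera also takes its p on the 4 residual degrees of freedom, so a call can be lost without correlation between genes. A list is said to be called where camera at the preset correlation called it, unless another test is named. Of 805 list members 795 were on the array, and 44 of the 693 tested genes are in several lists. Counts within a list are given over all genes tested and adjusted over the list alone. List medians were the same with genes dim in 1 group set to their bound. List means use the fitted values, and with such bounds those of the macrophage maturation and erythroid lists were -0.36 and -0.08. The design, the lists, the rule for named genes and the first alternatives were fixed before the data were examined. The rule names the 10 highest and 10 lowest log2 fold changes among changed genes whose groups do not overlap and which lie above background on at least 1 array of each group, the 5 highest and 5 lowest bounds, up to 4 members of each list with the lowest p and the called member with the lowest p in the lesser direction, the genes that rank first in each direction in the lists of other cell types, and Ifnar1, Ifnar2 and Csf1r, with symbols only in the first and second of these parts. A few genes that this rule names are not reported here.

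Alternatives tried were quantile normalization, normexp background correction (offset 50) with percentile scaling or quantile normalization, the deposited table, no filter on dim probes, a filter that asks for all 6 arrays, the mean of all probes of a gene, eBayes with trend and robust, array weights, the replicate number as a block, slide as a block, treat at 1.5-fold, and leaving out each array. Control 3 as the lone control, the arrays of slide 1 alone, scaling on the median of probes well above background on all 6 arrays and scaling on the E1A spike-ins (the mean log2 signal of the 6 brightest after the brightest) were added after seeing the data. The spike-ins were brighter on controls 1 and 2 (mean 4495 and 4135) than on control 3 (2135) and the IFN-beta arrays (2273, 2411 and 2082). Slide and scan coincide, and slide 2 holds only IFN-beta samples.

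Controls 1 and 2 were checked for being 1 sample hybridised to 2 arrays. Their difference had a spread of 0.110 over genes, 1.50 times that of replicate spots within the arrays, against 1.85 to 2.37 times between IFN-beta arrays. Of 7 hepatocyte markers, 6 lay above background on control 1, 3 on control 2 and 0 elsewhere, which is the reason for keeping the arrays as 2 samples. Whether they are separate RNA preparations stays open. If they are not, the p-values rest on 2 control samples and not on 3, and those without control 3 on 1. Marker lists of other tissues (fibroblast, smooth muscle, fat cell, cartilage and bone, endothelium, red cell, skeletal muscle, hepatocyte, neuron and epidermis) and 11 further gene lists (LXR targets, fatty acid synthesis, ATF4 targets, endoplasmic reticulum chaperones, ribosome biogenesis, ribosomal proteins, and the Schlafen, membrane-spanning 4A, tripartite motif, poly-ADP-ribose polymerase and lymphocyte antigen 6 families) were chosen after seeing the data, and their results stand in the closing section.

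The tests were tried on simulated data with the spread of the real arrays, in 10 simulations with 200 of 19500 genes changed between the groups. Of the changed genes, 0.2% were recovered at a log2 fold change of 0.5, 13.6% at 1, 79.6% at 2 and 94.6% at 3, and 4.57% of the calls were false. All 30 lists shifted by 0.5 were recovered, and none of 410 tests of lists without a shift gave a call. All 6 simulated arrays varied alike, whereas the real controls 1 and 2 nearly coincided and control 3 lay far from them. The shares recovered and the 4.57% may therefore not hold for the real arrays. Genes also varied independently in the simulation, whereas the correlation estimated between genes of the real lists reached 0.88. The simulation is therefore no guide to false list calls. Other splits of the real arrays into 3 and 3 called from 6 to 19 lists.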

Results

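Monocytes from the bone marrow of C57BL/6J mice, purified by magnetic sorting, were kept for 60 h in 20 ng/mL M-CSF, the growth factor that drives monocytes towards macrophages. The cultures received either no further addition (control) or 100 U of IFN-beta, a type I interferon. RNA of 3 control and 3 IFN-beta samples was labelled with Cy3 and hybridised to 1 array each, and each array measured 56605 probes. The 75th percentile of the processed signal was 549, 528 and 305 on controls 1, 2 and 3, and 244, 236 and 242 on the IFN-beta arrays. Of the probes, 63.9%, 63.3% and 52.5% lay well above background on controls 1, 2 and 3, against 52.5%, 51.5% and 49.0% on IFN-beta 1, 2 and 3, and no probe was saturated. Slide 1 held the 3 controls and IFN-beta 1, and slide 2 held IFN-beta 2 and 3, a single group. Nothing in the labels says that the replicates came from separate mice or cultures, so the limma p-values of genes measure only the spread between these samples, and the number of arrays limits the precision. Camera's p-values at the preset correlation of 0.01 do not measure that spread where genes of a list vary together. The estimated correlation was 0.79 for antiviral, 0.85 for replication and 0.78 for cholesterol genes, and below the preset in some other lists.

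The IFN-beta arrays formed a tight group and the controls did not. On the first principal component of the tested genes (72.2% of the variance), controls 1 and 2 lay at -92.0 and -93.5, control 3 at -3.87, and the IFN-beta arrays between 59.5 and 65.4. The second component (16.1%) set control 3, at -73.4, apart from the rest. Across genes, which are not independent replicates, control 3 correlated more closely with the IFN-beta arrays (r from 0.963 to 0.966) than with controls 1 and 2 (r = 0.957 and 0.956). The order was the reverse for a robust spread of the differences over 17522 genes well above background on all arrays. By that measure control 3 differed from controls 1 and 2 by 0.332 and 0.351, and from IFN-beta 1, 2 and 3 by 0.474, 0.511 and 0.493. Transcripts of connective tissue were bright on controls 1 and 2 alone: the median over 17 fibroblast markers was 3.72 and 3.54 on these arrays, against -6.34 on control 3 and from -5.86 to -4.97 with IFN-beta (log2 signal minus the array's 75th percentile). List medians against control 3 alone are therefore given beside the comparison of the groups, and so are levels of many genes. All 36 measured antiviral genes were lower on control 3 than on every IFN-beta array.

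**Figure D1:**
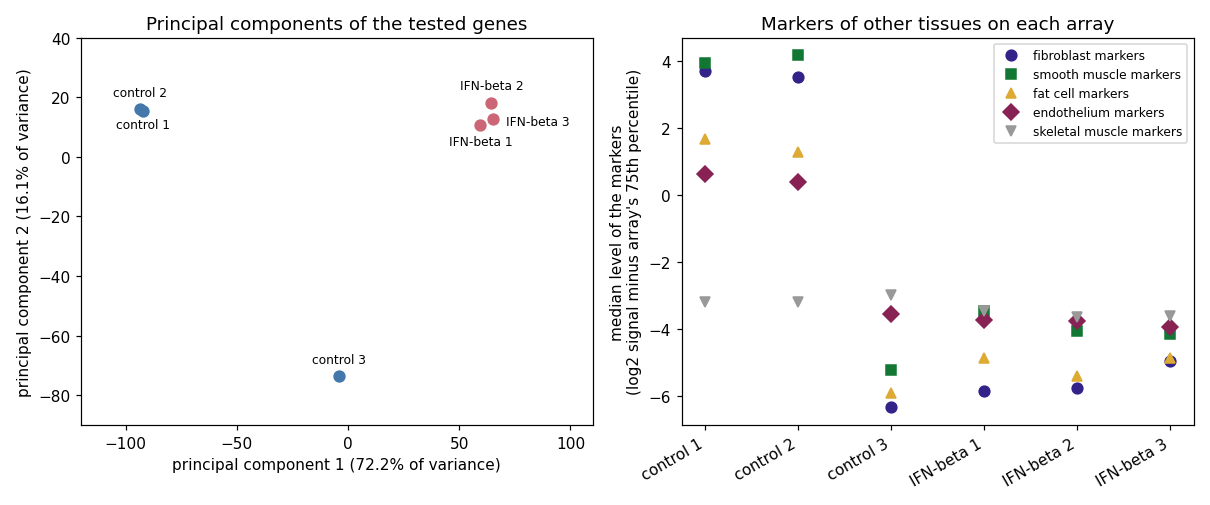
Left, the first 2 principal components of the tested genes, each point an array. Right, the median level of marker lists of other tissues on each array (log2 signal minus the array's 75th percentile). Controls 1 and 2 lie together, control 3 lies apart from them and from the IFN-beta arrays, and fibroblast, smooth muscle, fat cell and endothelium markers are high on controls 1 and 2 and low on the other 4 arrays.

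The comparison asks what a type I interferon does to the transcripts of monocytes that mature in M-CSF. Interferon-stimulated genes rose throughout: all 36 antiviral genes measured were higher, with a median log2 fold change of 3.32, and all 16 interferon-inducible GTPases, with a median of 2.86. The largest single rise among named genes measured in both groups was that of Arg1, arginase 1, by at least 212-fold. Of 23 genes for cholesterol synthesis and uptake, 18 fell and none rose (median -0.87), and Cd209a, which encodes a lectin of the DC-SIGN family, fell at least 37.9-fold. Of the genes of the unfolded protein response 10 of 18 rose, of the neutrophil markers 13 of 18 and of the basophil, mast cell and eosinophil markers 11 of 15. With an estimated correlation no list was called, antiviral genes, GTPases and cholesterol genes (adjusted p = 0.459, 0.356 and 0.605) included. Correlation between genes is not the sole reason. Chemokines and alternative activation markers, with estimated correlations of -0.0012 and -0.042, below the preset, lost their calls there too (camera adjusted p = 0.459 for both). Genes such as Itga8 fell mainly against controls 1 and 2.

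In limma, 3866 of 19500 genes changed at an adjusted p under 0.05, 2301 of them higher and 1565 lower with IFN-beta, and 2272 changed at least 2-fold (1311 higher, 961 lower). The 2 groups did not overlap for 40.2% of the tested genes, and the median of all genes was 0.10. Interchangeable arrays would give 10% on average. That average is no test of the 40.2%, because genes vary together and controls 1 and 2 were nearly alike. Of the 3866 genes, 1478 were called in the same direction against controls 1 and 2 alone and against control 3 alone (797 higher, 681 lower). The count depended on single arrays: it was 10939 without control 3, 1830 without control 1, 2018 without control 2, 1857 without IFN-beta 2 and 2112 without IFN-beta 3, and the count at 2-fold or more was 5230 without control 3. Without control 3 the controls were 1 and 2 only, which differed little and may be 1 RNA preparation. Counts and p-values without control 3, here and below, may therefore overstate what changed. With slide as a block, which leaves IFN-beta 1 alone against the controls, 1040 genes changed, and within slide 1, 295. The share of higher genes among those changed was 59.5%, but 27.8% when arrays were scaled on the spike-in controls, which moved the median of all genes to -0.19, and 69.9% after normexp background correction with percentile scaling, with a median of 0.18. Of the genes changed at least 2-fold, 1785 rose and 3445 fell without control 3, and 850 rose and 2066 fell with spike-in scaling.

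**Figure D2:**
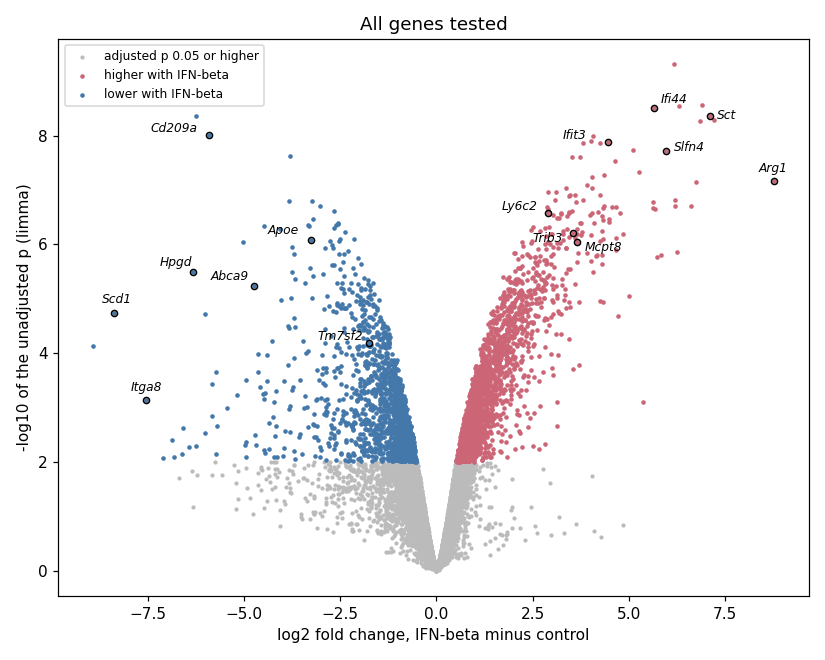
Log2 fold change (IFN-beta minus control) against -log10 of the unadjusted limma p for the 19500 genes tested. Red and blue points are the 2301 genes higher and the 1565 genes lower at an adjusted p under 0.05, and named genes are circled, from Scd1 and Itga8 at the left to Arg1 at the right.

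Among genes measured in both groups, the 10 highest by fitted log2 fold change were Arg1, Apol9b, Rab15, Ccl12, Slfn4, Apol9a, Ifi44, Slfn1, Gbp6 and H2-Q5. Arg1 (probe at chromosome 10, 24636194 to 24636253, mm9) was well above background on 1 of 3 controls and on every IFN-beta array (adjusted p = 5.53e-05). Only a bound therefore holds, at least 212-fold and at least 150-fold against control 3. Apol9b rose by 6.25 ± 0.46 (log2 fold change ± SE, 3 arrays per group, as for all genes, adjusted p = 1.90e-04), and Rab15, which encodes a small GTPase of endosomes, by 6.21 ± 0.36 (adjusted p = 8.30e-05). Slfn4 and Slfn1, of the interferon-inducible Schlafen family, rose by 5.98 ± 0.25 and 5.64 ± 0.33. Gbp6, not well above background on control 3, rose by 4.01 against controls 1 and 2, and its adjusted p over all controls was 0.00989, or 0.121 with slide as a block. Over all controls the bound for Gbp6 was at least 24.6-fold, a log2 fold change of 4.62, which would put it below H2-Q5. H2-Q5, a class I histocompatibility gene, rose by 4.77 ± 0.28. Apol9a and Apol9b, the Schlafen, H2-Q and Gbp genes and Ifi213 and Ifi214 belong to families of near-identical sequence, so single members are uncertain.

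Of the changed genes, 53 were not well above background on any control and 257 on any IFN-beta array, and for these only a bound can be given. Ifi214 rose at least 64.8-fold, Sct, which encodes the hormone secretin, at least 62.5-fold, Grm6, a glutamate receptor gene, at least 25.1-fold, Ifi213 at least 19.7-fold and Nrip3 at least 8.67-fold. In the other direction, Scd1 (stearoyl-CoA desaturase, probe at chromosome 19, 44469387 to 44469446) fell at least 111-fold, or at least 21.1-fold against control 3. Bounds of at least 80.4-fold for Ltbp2 and 56.2-fold for Myh11, genes of extracellular matrix and smooth muscle, rested on controls 1 and 2. Against control 3 they fell at least 1.82-fold and 1.79-fold (adjusted p = 0.183 and 0.0611). Without control 1 the adjusted p rose to 0.12 and 0.109. Both calls were also lost without any other array except control 3 (adjusted p from 0.0986 to 0.138).

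The 10 lowest genes measured in both groups, by fitted log2 fold change, were Itga8, Hpgd, Npdc1, Crip2, Fzd1, Cavin1, Abca9, Plpp1, Kazald1 and Plcd1. For 8 of them the controls differed among themselves. Itga8, an integrin gene (probe at chromosome 2, 12028462 to 12028521), stood at 4.67, 5.30 and -0.63 on controls 1, 2 and 3, so that its fall of at least 151-fold (adjusted p = 0.00957) was at least 11.3-fold against control 3. Crip2 and Cavin1, at -4.95 ± 1.39 and -4.94 ± 1.23, were -1.14 and -1.57 against control 3, and their calls were lost without any 1 array other than control 3 (adjusted p from 0.0669 to 0.117). The call of Npdc1 (-5.44 ± 1.06, or -2.64 against control 3) was lost without IFN-beta 2 (adjusted p = 0.0501). Hpgd, the enzyme that inactivates prostaglandins, and Abca9, a lipid transporter gene, were level across the controls. Hpgd fell at least 31.9-fold (adjusted p = 3.22e-04) and Abca9 at least 15.5-fold (adjusted p = 4.52e-04), or at least 44.4-fold and 17.4-fold against control 3. Itga8, Hpgd, Fzd1 and Abca9 were well above background on 3 controls and on 1 IFN-beta array, and Plpp1 on 3 controls and 2 IFN-beta arrays. For these genes only bounds on the falls hold (at least 23.3-fold for Fzd1 and 24.9-fold for Plpp1), and these would change the order.

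**Figure D3:**
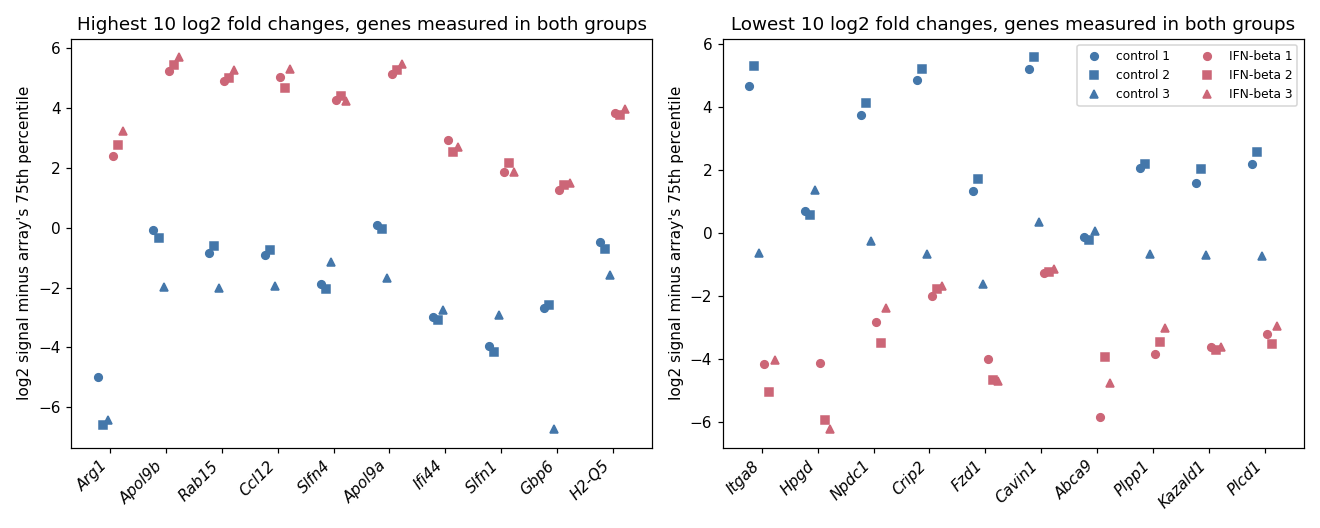
Level of each gene on each array (log2 signal minus the array's 75th percentile), blue for controls and red for IFN-beta, for the 10 highest and the 10 lowest log2 fold changes among changed genes measured in both groups. For 8 of the 10 lowest genes control 3 lies between the other controls and the IFN-beta arrays, whereas for Hpgd and Abca9 the 3 controls lie together.

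The antiviral programme rose as a whole. Each of its 36 genes was higher, over all genes and adjusted over the list alone, and the list had a median of 3.32 (camera adjusted p = 2.39e-29, and adjusted p = 0.459 with an estimated correlation), with 2.84 against control 3 alone and 3.30 within slide 1 and with slide as a block. Ifi44 rose by 5.66 ± 0.19, Ifit3b by 4.65 ± 0.21, Ifit3, whose protein binds viral RNA complexes, by 4.47 ± 0.18, and Isg20, an exonuclease gene, by 3.80 ± 0.15, with adjusted p from 1.28e-05 to 2.89e-05. The 16 measured interferon-inducible GTPases, which attack the vacuoles of intracellular microbes, also all rose over all genes and adjusted over the list alone, with a median of 2.86 (camera adjusted p = 3.38e-15, and adjusted p = 0.356 with an estimated correlation). It was 2.48 against control 3 alone and 2.87 within slide 1 and with slide as a block. Tgtp2 (4.07 ± 0.16), Gbp8 (3.29 ± 0.23), Gbp4 (2.92 ± 0.19) and Gbp9 (2.91 ± 0.20) had the lowest p in this list.

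Of 20 genes for interferon receptors and signalling, 7 rose and none fell, or 7 rose and 1 fell adjusted over the list alone, and 14 rose and 1 fell without control 3. Their median was 0.43 (camera adjusted p = 0.00196, and adjusted p = 0.758 with an estimated correlation), with 0.14 against control 3 alone and 0.41 within slide 1 and with slide as a block. The members that rose included Irf7, a transcription factor that amplifies interferon production (4.32 ± 0.30), Socs1, an inhibitor of the same pathway (3.52 ± 0.15), Stat2 (2.77 ± 0.23) and Jak2 (1.83 ± 0.21). The receptor genes did not pass the test. Ifnar1 was at 0.41 ± 0.17 (adjusted p = 0.122) and Ifnar2 at 0.24 ± 0.23 (adjusted p = 0.48). Without control 3 both were called higher, at 0.52 (adjusted p = 0.0132) and 0.48 (adjusted p = 0.0204), and the sign of Ifnar2 turned on another scaling. Csf1r, the receptor for M-CSF, was at 0.07 ± 0.20 (adjusted p = 0.836), again with a sign that depended on the scaling. Of the other probes of Ifnar1, 3 had the opposite sign, and 1 of Csf1r.

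Genes for antigen presentation on MHC class I rose, and those for class II shifted slightly downwards as a list, not in every setting. Of 22 class I genes, 19 rose and none fell (20 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 8.94e-12, and adjusted p = 0.459 with an estimated correlation). That median was 1.19 against control 3 alone and 1.25 within slide 1 and with slide as a block. H2-T10 rose by 2.46 ± 0.24, H2-T24 by 2.23 ± 0.18, H2-T22 by 2.18 ± 0.18, and Tap1, which encodes part of the peptide transporter of the endoplasmic reticulum, by 2.02 ± 0.19. Of 11 class II genes, 3 fell and none rose, both over all genes and adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.0373, and adjusted p = 0.758 with an estimated correlation). It was -0.63 against control 3 alone and -0.45 within slide 1 and with slide as a block. The genes that fell were Ciita, the class II transactivator (-1.31 ± 0.23), H2-Eb1 (-0.76 ± 0.22) and H2-Ab1 (-0.67 ± 0.18), while Ctss, a protease that processes the class II invariant chain, was at 0.45 ± 0.18 (adjusted p = 0.111, or 0.00992 without control 3), a sign that turned on another scaling. The class II shift was not called without control 3 (median -0.17, adjusted p = 0.475), without IFN-beta 1 (median -0.29, adjusted p = 0.114), with spike-in scaling (median -0.59, adjusted p = 0.0621) or with array weights (median -0.21, adjusted p = 0.115). The calls of H2-Ab1 and H2-Eb1 were lost without any 1 array other than control 3 (adjusted p from 0.0819 to 0.115). The difference between the 2 classes was not tested.

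Sensors of foreign nucleic acid shifted upwards as a list. Of 16 genes for cytosolic and Toll-like sensors, 7 rose and none fell (9 adjusted over the list alone, 12 rose without control 3), with a median of 0.79 (camera adjusted p = 1.65e-04, and adjusted p = 0.758 with an estimated correlation). That median was 0.33 against control 3 alone and 0.73 within slide 1 and with slide as a block. Those that rose included Zbp1 (4.30 ± 0.28) and the RNA helicase genes Ddx58 (2.83 ± 0.20), Dhx58 (2.65 ± 0.23) and Ifih1 (2.58 ± 0.22). The other pattern recognition receptors had no common direction: 1 of 14 rose and 2 fell (2 and 2 adjusted over the list alone, 7 and 3 without control 3), with a median of 0.27 (-0.15 against control 3), a mean of 0.02 and camera adjusted p = 0.847, and the sign of the median turned on another scaling. Cd14, the co-receptor for lipopolysaccharide, fell by 1.81 ± 0.25. Clec7a rose (0.92 ± 0.19) and Tlr2 fell (-0.92 ± 0.25), and both calls were lost without control 1, control 2, IFN-beta 2 or IFN-beta 3 (adjusted p from 0.0526 to 0.13), that of Tlr2 also without IFN-beta 1 (adjusted p = 0.0661).

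Genes of inflammasomes and lytic cell death shifted upwards: 5 of 16 rose and none fell (9 adjusted over the list alone, 13 rose without control 3), with a median of 0.62 (camera adjusted p = 0.00194, and adjusted p = 0.758 with an estimated correlation). It was 0.20 against control 3 alone and 0.61 within slide 1 and with slide as a block. Ifi205 (3.67 ± 0.27) and Ifi204 (2.22 ± 0.26), of the DNA-binding Ifi200 family, Mlkl, the executor of necroptosis (1.75 ± 0.20), and Casp4, the sensor of cytosolic lipopolysaccharide (1.28 ± 0.18), had the lowest p. Regulators of apoptosis were not called as a list (median 0.40, camera adjusted p = 0.0814, or 0.0228 without control 3), although 6 of 21 rose and 1 fell (8 and 1 adjusted over the list alone, 13 and 2 without control 3, median 0.15 against control 3). Tnfsf10, which encodes the death ligand TRAIL, rose by 2.37 ± 0.30, and Bcl2a1d, of an anti-apoptotic family, by 1.76 ± 0.19. Fas was the member that fell (-1.54 ± 0.41). Its call was lost without any 1 array other than control 3 (adjusted p from 0.079 to 0.112), it was -0.51 against control 3, and 1 of its other probes had the opposite sign.

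Chemokine genes changed in both directions. Of 17, 8 rose and 2 fell (9 and 3 adjusted over the list alone, 10 and 7 of 20 without control 3), with a median of 0.69 (camera adjusted p = 0.0387, and adjusted p = 0.459 with an estimated correlation). That median was 0.80 against control 3 alone and 0.82 within slide 1 and 1.02 with slide as a block. Ccl12 rose by 6.20 ± 0.34, Ccl7 by 4.49 ± 0.28, Ccl24 by 2.33 ± 0.24 and Ccl2, the main attractant of monocytes, by 2.21 ± 0.24, and Cxcl16, which encodes a membrane-bound chemokine, fell (-1.30 ± 0.24). The shift was not called without control 3 (median 0.43, adjusted p = 0.684), without IFN-beta 1 (adjusted p = 0.0546) or within slide 1 (adjusted p = 0.0791), and passed in 12 of 22 settings. Of 18 genes for cytokines and their antagonists, 9 rose and none fell (10 adjusted over the list alone, 16 rose without control 3), with a median of 0.79 (camera adjusted p = 1.73e-04, and adjusted p = 0.459 with an estimated correlation). It was 0.26 against control 3 alone and 0.70 within slide 1 and 0.69 with slide as a block. Members that rose included Tnfsf10, Csf1, which encodes M-CSF itself (2.33 ± 0.40), Ltb (1.62 ± 0.25) and Il12b, an interleukin subunit shared by several cytokines (1.56 ± 0.20).

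Among co-stimulatory and co-inhibitory molecules, 7 of 16 rose and none fell (9 adjusted over the list alone, 10 rose without control 3), with a median of 0.71 (camera adjusted p = 0.0288, and adjusted p = 0.784 with an estimated correlation). That median was 0.28 against control 3 alone and 0.69 within slide 1 and with slide as a block. The shift was not called within slide 1 (adjusted p = 0.0554) or against control 3 alone (adjusted p = 0.14), and passed in 14 of 22 settings. The rises with the lowest p were those of the genes for the ligands of the programmed death receptor Pdcd1lg2 (2.49 ± 0.21) and Cd274 (2.27 ± 0.27), of Lgals9, a galectin gene (1.97 ± 0.20), and of Pilrb1 (1.33 ± 0.23).

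Markers of monocyte and macrophage stages split by gene. Of 20 classical monocyte markers, 6 rose and 2 fell (6 and 4 adjusted over the list alone, 9 and 3 without control 3), and the list was not called (median 0.17, or -0.21 against control 3, camera adjusted p = 0.278), with a sign that turned on another scaling. Ly6c2 and Ly6c1, the surface antigens of this stage and close paralogs, rose by 2.89 ± 0.17 and 2.68 ± 0.18, Plac8 by 3.51 ± 0.21 and Chil3, a chitinase-like gene, by 1.81 ± 0.24. Itgam, the CD11b integrin chain, fell (-0.72 ± 0.16), a call lost without control 1, control 2, IFN-beta 2 or IFN-beta 3 (adjusted p from 0.0608 to 0.101), and its other probe had the opposite sign. Of 19 non-classical monocyte markers, 1 rose and 4 fell (2 and 4 adjusted over the list alone, 8 and 5 without control 3), with a median of 0.06 (0.11 against control 3), a mean of -0.26 and camera adjusted p = 0.673, and a median whose sign turned on another scaling. Cx3cr1, the fractalkine receptor, fell by 1.44 ± 0.24, and Itgax, the CD11c integrin chain, by 1.88 ± 0.22.

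Of 32 macrophage maturation markers, 2 rose and 8 fell (4 and 10 adjusted over the list alone), and without control 3, 14 rose and 10 fell. The list was not called (camera adjusted p = 0.516), and its median of 0.21, whose sign turned on another scaling, and its mean of -0.42 differed in sign. Against control 3 its median was -0.11. Apoe, apolipoprotein E, fell by 3.27 ± 0.23 and Selenop, a selenium carrier, by 2.17 ± 0.18, with -2.88 and -2.02 against control 3. Cd163, the haemoglobin scavenger receptor, fell at least 4.85-fold, a bound that rested on controls 1 and 2 (at least 1.27-fold against control 3). Fcgr1, the high-affinity receptor for immunoglobulin G, rose by 2.20 ± 0.27. The wider list of phagocytic, Fc and scavenger receptors was not called either (4 of 19 rose and 6 fell, or 5 and 7 adjusted over the list alone, 7 and 9 of 21 without control 3, with a median of 0.15 and a mean of -0.06, camera adjusted p = 0.597). In it Axl, a receptor for apoptotic cells (1.90 ± 0.18), and Fcgr4 (1.87 ± 0.22) rose and Fcgrt, the neonatal Fc receptor gene, fell (-2.27 ± 0.21). The median of this list turned sign on another scaling, and was -0.32 against control 3.

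Alternative activation markers and genes of arginine, tryptophan and NAD metabolism shifted upwards as lists, and Arg1 is in both. Of 13 alternative activation markers, 8 rose and 2 fell (9 and 2 adjusted over the list alone, 8 and 4 of 15 without control 3), with a median of 1.07 (camera adjusted p = 0.0165, and adjusted p = 0.459 with an estimated correlation). It was 1.27 against control 3 alone and 0.83 within slide 1 and 0.95 with slide as a block. Mgl2, a macrophage lectin gene, rose by 1.72 ± 0.15, as did Pdcd1lg2, while Cd209a (probe at chromosome 8, 3743481 to 3743540) and Cd163 fell. The shift was not called without control 3 (median 0.69, adjusted p = 0.475), within slide 1 (adjusted p = 0.101), with no filter on dim probes (adjusted p = 0.326) or with array weights (adjusted p = 0.226). Of 14 genes of NAD, arginine and tryptophan metabolism and nitric oxide, 7 rose and none fell (8 and 3 adjusted over the list alone, 11 and 2 without control 3), with a median of 1.02 (camera adjusted p = 0.0033, and adjusted p = 0.459 with an estimated correlation). That median was 0.55 against control 3 alone and 1.08 within slide 1 and with slide as a block. Besides Arg1, Ass1, which makes argininosuccinate (2.51 ± 0.16), Acod1, the source of itaconate (2.38 ± 0.26), and Ido1, which degrades tryptophan (2.07 ± 0.23), had the lowest p.

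Genes for cholesterol synthesis and uptake fell together. Of 23, 18 fell and none rose (19 fell adjusted over the list alone), with a median of -0.87 (camera adjusted p = 2.67e-09, and adjusted p = 0.605 with an estimated correlation). It was -1.40 against control 3 alone and -0.89 within slide 1 and with slide as a block. Tm7sf2, a sterol reductase gene, fell by 1.74 ± 0.22 (adjusted p = 0.00192), Stard4, a sterol carrier gene, by 1.49 ± 0.22 and Fdft1, squalene synthase, by 1.37 ± 0.27. With slide as a block 1 of the 23 passed the test as a single gene. Genes of cholesterol efflux and oxysterols were not called as a list (1 of 12 rose and 3 fell, or 2 and 4 adjusted over the list alone, 4 and 5 without control 3, median -0.21, -0.30 against control 3, camera adjusted p = 0.199). They passed in 2 of 22 settings. Abca1, the main cholesterol exporter of macrophages, fell by 2.84 ± 0.52, or -1.49 against control 3.

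Lysosomal genes shifted upwards by a small amount. Of 28, 5 rose and 1 fell (6 and 1 adjusted over the list alone, 16 and 1 without control 3), with a median of 0.38 (camera adjusted p = 0.0125, and adjusted p = 0.784 with an estimated correlation). That median was 0.13 against control 3 alone and 0.35 within slide 1 and with slide as a block. The shift was not called with slide as a block (adjusted p = 0.161), within slide 1 (adjusted p = 0.229) or against control 3 alone (adjusted p = 0.122), and passed in 15 of 22 settings. Ctsz, a cathepsin gene (0.96 ± 0.19), and Npc2, a sterol carrier gene (0.93 ± 0.20), rose, and each call was lost without control 1, IFN-beta 2 or IFN-beta 3 (adjusted p from 0.0542 to 0.0825) and without control 2 (adjusted p = 0.0603 and 0.0737). Scarb2 fell (-0.61 ± 0.17), but its other probe and another background correction gave the opposite sign, and the call was lost without any 1 array other than control 3 (adjusted p from 0.078 to 0.167).

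Glycolysis, oxidative phosphorylation and iron handling were not called, though oxidative phosphorylation passed in 3 of 22 settings. Of 20 glycolysis genes 3 rose and 2 fell, over all genes and adjusted over the list alone (6 and 2 without control 3, median 0.15, -0.10 against control 3, mean -0.03, camera adjusted p = 0.847). Aldoc, an aldolase gene, fell by 3.84 ± 0.21 (adjusted p = 7.82e-05, and -4.20 against control 3), and Pfkfb3, which activates glycolysis, rose by 0.88 ± 0.15. Of 27 genes of oxidative phosphorylation 1 rose, on both counts (4 rose without control 3), with a median of 0.01 (-0.29 against control 3, camera adjusted p = 0.717), and the median of either list turned sign on another scaling. The gene was Cycs, cytochrome c (1.04 ± 0.21), whose call was lost without control 1, control 2 or IFN-beta 3 (adjusted p from 0.0565 to 0.0624). Of 15 iron genes 3 rose and 3 fell (4 and 4 adjusted over the list alone, 6 and 4 without control 3, median -0.02, -0.34 against control 3, camera adjusted p = 0.717). Lcn2, lipocalin 2 (1.40 ± 0.21), rose, and Trf, transferrin (-1.54 ± 0.19), and Slc39a14, a metal importer gene (-1.08 ± 0.20), fell.

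Genes of the unfolded protein response shifted upwards: 10 of 18 were higher and none lower (13 adjusted over the list alone, 14 rose without control 3), with a median of 0.78 (camera adjusted p = 4.15e-05, and adjusted p = 0.459 with an estimated correlation), and 0.56 against control 3 alone and 0.71 within slide 1 and with slide as a block. The 4 with the lowest p, Trib3 (3.54 ± 0.24), Ddit3, which encodes CHOP (3.37 ± 0.17), Chac1 (2.14 ± 0.23) and Asns, asparagine synthetase (1.66 ± 0.18), are targets of the transcription factor ATF4. Targets and inhibitors of NF-kB shifted slightly downwards as a list: 3 of 17 fell and none rose (4 fell and 1 rose adjusted over the list alone, and 6 fell and 3 rose without control 3), with a median of -0.25 (camera adjusted p = 0.0387, and adjusted p = 0.758 with an estimated correlation), and -0.43 against control 3 alone and -0.30 within slide 1 and with slide as a block. That shift was not called without control 3 (median -0.16, adjusted p = 0.371), without IFN-beta 1 (median -0.22, adjusted p = 0.0805) or with spike-in scaling (median -0.54, adjusted p = 0.0752). Nor was it called with array weights (median -0.06, adjusted p = 0.0981) or with the mean of all probes of a gene (median -0.25, adjusted p = 0.0517). The members that fell were Nfkb2 (-0.75 ± 0.15), Nfkbie (-0.93 ± 0.21) and Icam1, an adhesion molecule (-0.64 ± 0.16), and all 3 calls were lost without IFN-beta 3 (adjusted p from 0.0533 to 0.0748). The calls of Nfkb2 and Icam1 were lost without control 1 or control 2 (adjusted p from 0.0565 to 0.111), those of Nfkbie and Icam1 without IFN-beta 2 (adjusted p = 0.0791 and 0.114), and that of Icam1 without IFN-beta 1 (adjusted p = 0.088).

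Immediate early and heat shock genes were not called as a list (2 of 17 rose, or 3 rose and 6 fell adjusted over the list alone, 4 and 5 without control 3, median 0.02, 0.02 against control 3, mean -0.56, camera adjusted p = 0.455), and the sign of the median turned on another scaling. The heat shock genes Hspa1b and Hspa1a were at -4.29 ± 1.26 (adjusted p = 0.0505) and -3.44 ± 1.07 (adjusted p = 0.0599). They were -0.85 and -0.53 against control 3, and without control 3 both were called lower (adjusted p = 2.06e-05 and 2.63e-05).

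Genes of DNA replication shifted upwards as a list, to a degree that depended on control 3. Of 35 genes of G1/S and DNA replication, 6 rose and none fell (12 adjusted over the list alone), while 28 rose without control 3 and 1 fell against control 3 alone. The list had a median of 0.54 (camera adjusted p = 0.00194, and adjusted p = 0.792 with an estimated correlation), and 0.03 against control 3 alone and 0.49 within slide 1 and with slide as a block. The shift was not called against control 3 alone (adjusted p = 0.363). Dut (1.08 ± 0.24), Cdc45 (1.13 ± 0.25), Ccne1, cyclin E1 (1.04 ± 0.24), and Mcm10 (1.06 ± 0.25) rose, and each call was lost without control 1, control 2, IFN-beta 2 or IFN-beta 3 (adjusted p from 0.0508 to 0.0981), and all but that of Cdc45 without IFN-beta 1 (adjusted p from 0.0561 to 0.0605). Of 40 genes of G2/M and mitosis 1 fell, on both counts, with a median of 0.05, whose sign turned on another scaling, and a mean of -0.01 (camera adjusted p = 0.455). The gene was Anln, which encodes anillin (-0.97 ± 0.18), and without control 3, 13 rose and 1 fell. The list's median was 0.33 without control 3 (camera adjusted p = 0.032, higher) and -0.57 against control 3 alone. Its estimated correlation between genes was 0.88, far above the preset 0.01, so that p does not measure the spread between samples. Targets of p53 went both ways (5 of 19 rose and 3 fell, or 6 and 3 adjusted over the list alone, 9 and 7 of 20 without control 3, median 0.34, 0.11 against control 3, mean -0.02, camera adjusted p = 0.824): Sesn2 rose by 1.39 ± 0.17, and Sesn1 and Zmat3 fell (-1.99 ± 0.19 and -1.40 ± 0.21). Genes of osteoclast differentiation were not called (2 of 17 rose and 2 fell, or 3 and 2 adjusted over the list alone, 4 and 4 without control 3, median -0.02, -0.23 against control 3, camera adjusted p = 0.717), with Itgb3, the beta 3 integrin chain, at 1.13 ± 0.19.

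Most markers of granulocytes rose. Of 18 neutrophil markers, 13 rose and none fell, over all genes and adjusted over the list alone, with a median of 1.47 (camera adjusted p = 1.59e-07, and adjusted p = 0.583 with an estimated correlation), and 1.04 against control 3 alone and 1.63 within slide 1 and with slide as a block. Ly6g rose by 2.88 ± 0.16, and the granule genes Prtn3, Mpo and Ctsg by 2.87 ± 0.23, 2.80 ± 0.27 and 2.27 ± 0.27. Of 15 markers of basophils, mast cells and eosinophils, 11 rose and none fell on both counts (11 and 2 of 16 without control 3), with a median of 2.49 (camera adjusted p = 2.74e-06, and adjusted p = 0.459 with an estimated correlation), and 2.25 against control 3 alone and 2.73 within slide 1 and 2.78 with slide as a block. The basophil protease gene Mcpt8 rose by 3.66 ± 0.26, Fcer1a, a chain of the receptor for immunoglobulin E, by 3.42 ± 0.28, Cpa3, mast cell carboxypeptidase, by 3.36 ± 0.28, and Hdc, which makes histamine, by 2.79 ± 0.24. Of 8 haematopoietic progenitor markers 4 rose on both counts (6 and 3 of 12 without control 3), among them Gata2 (2.36 ± 0.23), Kit (1.41 ± 0.21) and Myb (1.88 ± 0.28). That list was not called (median 0.62, camera adjusted p = 0.0708), with a median of 0.64 against control 3 alone. It was called by fry (adjusted p = 0.0023), and by camera with spike-in scaling (adjusted p = 0.0227) and without control 1, control 2 or IFN-beta 3 (adjusted p = 0.028, 0.0269 and 0.0273). Gata1, a transcription factor of red cells, mast cells and eosinophils, rose by 4.05 ± 0.24. The erythroid list was not called (2 of 8 rose, 3 adjusted over the list alone, 2 and 5 of 11 without control 3, median 0.37, mean -0.11, camera adjusted p = 0.516). Its direction depended on control 3: its median was 0.68 against control 3 alone and -0.27 without control 3.

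Camera at its preset correlation called no list of lymphocyte or dendritic cell markers in the comparison of the groups. By fry, 3 were called: T and NK cells (adjusted p = 0.0464), plasmacytoid (adjusted p = 0.0332) and conventional dendritic cells (adjusted p = 0.0252). Of 13 T and NK cell markers, 5 rose and 2 fell on both counts (5 and 3 of 18 without control 3, median 0.36, camera adjusted p = 0.227). The list had a median of 1.17 against control 3 alone, and camera called it higher without control 1 (adjusted p = 0.028) or without IFN-beta 3 (adjusted p = 0.0391). Its median without control 3 was -0.01. Klrk1, an activating receptor gene (2.56 ± 0.23), Cd5 (1.57 ± 0.18) and Nkg7 (1.46 ± 0.16) rose, and Klrb1c fell at least 1.4-fold, with the opposite sign in its fitted change after another background correction. Of 10 plasmacytoid dendritic cell markers, 4 rose (4 rose and 1 fell adjusted over the list alone, 4 and 1 without control 3, median 0.09, -0.08 against control 3, camera adjusted p = 0.49), with Cox6a2 at 3.13 ± 0.19 and Klk1 at 1.90 ± 0.18. Of 13 conventional dendritic cell markers, 1 rose and 5 fell (3 and 6 adjusted over the list alone, 4 and 5 without control 3, median -0.53, -0.76 against control 3, camera adjusted p = 0.0594). By camera that list was called lower without control 2 (adjusted p = 0.0269) and without IFN-beta 2 (adjusted p = 0.0236). Its median was -0.68 with slide as a block and within slide 1. With probes well above background on all 6 arrays alone its median was 0.24 (adjusted p = 0.663). Cd209a and Itgax fell, Zbtb46, the lineage's transcription factor, fell at least 2.55-fold (at least 1.56-fold against control 3), and Ccr7, the receptor for homing to lymph nodes, rose by 3.04 ± 0.23. Of 7 B cell markers 1 rose, on both counts (1 and 1 of 9 without control 3, median 0.09, -0.01 against control 3, camera adjusted p = 0.923). Of 8 platelet markers 2 rose and 1 fell, on both counts (2 and 1 of 12 without control 3, median 0.09, 0.26 against control 3, camera adjusted p = 0.847), with a rise of at least 4.34-fold for Itga2b. The medians of the B cell, plasmacytoid and platelet lists turned sign on another scaling.

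Of 9 stromal and endothelial markers 1 rose, on both counts, and the list was not called (median -2.72, camera adjusted p = 0.173). Control 3 decided its direction: the median was -6.36 without control 3 (camera adjusted p = 2.43e-07) and 0.95 against control 3 alone. Col1a2, a collagen chain, was at -5.14 ± 2.20 (adjusted p = 0.136) and at 0.88 against control 3. Kdr, a receptor for vascular endothelial growth factor, was the member that rose (1.94 ± 0.21, adjusted p = 9.92e-04).

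By camera with its preset correlation, 19 of the 41 lists changed, 16 of them higher and 3 lower, and with an estimated correlation none did (3 at an unadjusted p under 0.05), while fry, which tests a list on its own, called 20. These were not the same lists. By fry, MHC class II, replication, lysosome, NF-kB and co-stimulation were not called (adjusted p = 0.264, 0.182, 0.102, 0.102 and 0.0594). Called by fry but not by camera were classical monocytes (adjusted p = 0.0229), p53 targets (adjusted p = 0.0441), T and NK cells, both dendritic cell lists and progenitors. With slide as a block 19 lists changed and within slide 1, 16. Of the 190 genes named by the rule, 167 were called, and 121 of these were called with each array left out in turn. Of the 190 genes, 42 lost their call against control 3 alone, 72 with slide as a block and 119 within slide 1, where a single IFN-beta array remains.

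**Figure D4:**
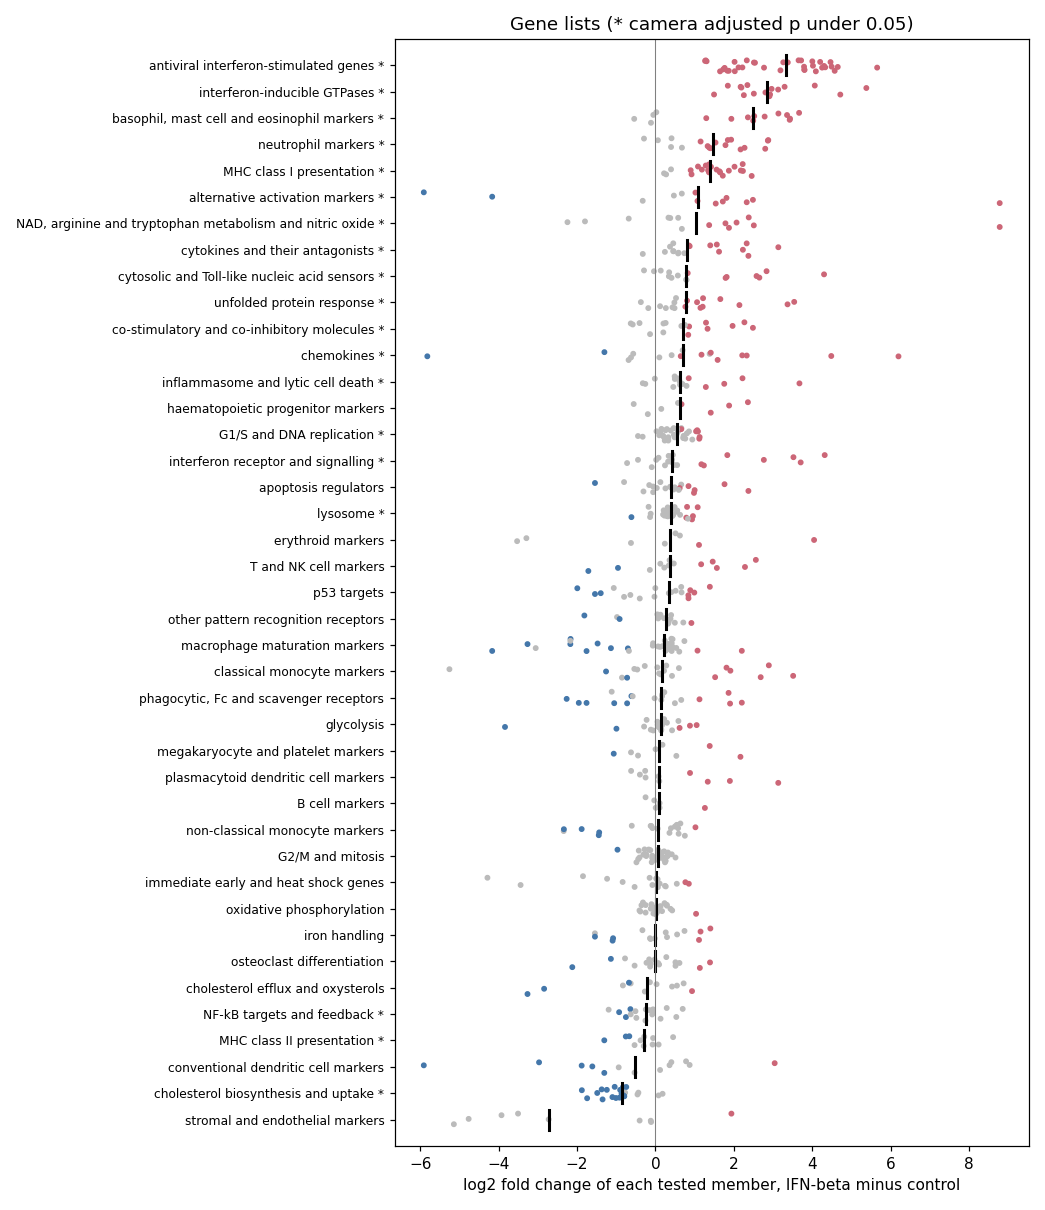
Log2 fold change of each tested member of the 41 lists (points, red for higher, blue for lower and gray for not called at an adjusted p under 0.05), with the list's median as a black bar and an asterisk where camera called the list. The medians run from -2.72 for stromal and endothelial markers to 3.32 for antiviral genes, and several medians near 0 changed sign with the scaling, among them those of glycolysis and oxidative phosphorylation.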

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

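Control 3 as the lone control, the arrays of slide 1 alone, scaling on the median of bright probes and spike-in scaling were chosen after seeing the data, the other alternatives before. Against 3866 changed genes, 12734 passed with array weights, 1697 with no filter on dim probes, 1024 with treat at 1.5-fold, 1040 with slide as a block, 295 within slide 1 and 1924 against control 3 alone. The weights went from 0.0745 for control 3 to 44.3 for control 1, and their estimation stopped before converging, so the counts with array weights rest mostly on control 1 on that side and are not a sound guide. The unfiltered test spans 37323 genes, treat asks for a larger change, and the slide and control settings leave 1 sample in an arm, which is then assumed to vary like the other arm. Leaving out 1 array gave from 1830 (without control 1) to 10939 genes (without control 3). Against 2272 genes changed at least 2-fold, 1496 passed after normexp with percentile scaling and 1276 after normexp with quantile normalization, where the offset of 50 narrows the folds of dim probes. There were 3524 with array weights, 1040 with slide as a block and 295 within slide 1, and from 1708 to 5230 with 1 array left out. The 19 lists became 0 with an estimated correlation and stayed between 15 and 21 otherwise, from 16 to 21 with 1 array left out.

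The share of higher genes was 59.5%, 69.9% after normexp with percentile scaling and 27.8% with spike-in scaling, where 997 rose and 2590 fell, because that scaling lowers the median of all genes to -0.19. The median was -0.01 when scaled on bright probes, 0.18 after normexp with percentile scaling and -0.11 against control 3. Of 3866 calls, 2556 were kept with spike-in scaling, and no direction turned there. Fewer were kept against control 3 alone and with slide as a block, which leave 1 sample in an arm. No direction could turn in those settings, because in all 3866 genes every IFN-beta array lay on the same side of every control. After normexp 3633 of the 3866 kept their direction with percentile scaling and 3860 with quantile normalization. Of the named genes, Scarb2 reversed to 0.51 after normexp with percentile scaling and 0.48 after normexp with quantile normalization, and Klrb1c to 0.18 after normexp with percentile scaling. The cause was not tested. Of the 19 lists, antiviral genes, GTPases, MHC class I, signalling, nucleic acid sensors, inflammasome, cytokines, cholesterol synthesis, NAD and arginine metabolism, unfolded protein response, neutrophil and basophil lists passed in all 22 settings with a preset correlation, replication genes in 21, MHC class II and alternative activation in 18, NF-kB in 17, lysosome in 15, co-stimulation in 14 and chemokines in 12.

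The groups share replicate numbers, but the labels do not say that a number marks a shared mouse or day, so samples were not treated as paired. Samples with the same number deviated together only weakly (r = 0.07, 0.02 and 0.07 over genes), though more than those with different numbers (r from -0.09 to 0.01). This cannot exclude pairing, because the gap between control 3 and the other controls dominates the deviations of the controls. With the replicate number as a block, 3271 genes changed, 2212 of them at least 2-fold, and 18 lists. As for signal over background, the IFN-beta arrays were dimmer than controls 1 and 2, and 257 of the changed genes are known only as a bound on the IFN-beta side and 53 on the control side, and falls below that level have no measured size.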

Other observations

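The further gene lists here, and every test in this part except the counts over splits of the arrays, were chosen after the results they bear on had been seen, and the genes named here were chosen after their values were seen. Of 26 targets of ATF4, the transcription factor of amino acid and endoplasmic reticulum stress, 20 rose and none fell, with a median of 1.10 (camera adjusted p = 8.99e-09, and adjusted p = 0.174 with an estimated correlation), 0.85 against control 3 alone and 1.09 within slide 1. They included Phgdh (1.98 ± 0.20), which starts serine synthesis, the amino acid transporter gene Slc7a5 (1.53 ± 0.18) and the tRNA synthetase gene Aars (1.62 ± 0.20), and 6 of the 26 are in the lists fixed earlier. Of 19 endoplasmic reticulum chaperones and partners, 13 of them in the earlier lists, 6 rose and 1 fell, with a smaller median of 0.49 (camera adjusted p = 0.0133, and adjusted p = 0.351 with an estimated correlation), or 0.34 against control 3. Genes of ribosome biogenesis rose (17 of 30, none fell, median 0.74 (camera adjusted p = 5.80e-08, and adjusted p = 0.351 with an estimated correlation), or 0.44 against control 3), such as Nolc1 (1.38 ± 0.20) and Rrp9 (1.35 ± 0.19). No gene among 28 for ribosomal proteins passed, with a median of 0.25 whose sign turned with spike-in scaling and against control 3 (-0.06, camera adjusted p = 0.146 for the groups). The difference between these lists was not tested.

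Genes of fatty acid synthesis fell along with those of cholesterol: 8 of 15 fell and none rose, with a median of -0.79 (camera adjusted p = 3.96e-07, and adjusted p = 0.0976 with an estimated correlation), -0.99 against control 3 alone and -1.08 within slide 1. Beside Scd1, Fads2 fell by 1.45 ± 0.25 and Fasn, fatty acid synthase, by 1.03 ± 0.16. Most members of 3 families rose: 7 of 7 Schlafen genes (median 2.68 (camera adjusted p = 7.82e-08, and adjusted p = 0.174 with an estimated correlation), or 2.29 against control 3), 10 of 12 membrane-spanning 4A genes (median 1.52 (camera adjusted p = 5.56e-07, and adjusted p = 0.174 with an estimated correlation), or 1.22 against control 3), among them Ms4a4b (3.61 ± 0.25) and Ms4a3 (3.46 ± 0.23), and 7 of 8 lymphocyte antigen 6 genes (median 2.56 (camera adjusted p = 4.19e-07, and adjusted p = 0.0976 with an estimated correlation), or 2.23 against control 3), with Ly6a at 3.11 ± 0.16. In the lists fixed earlier were 4 of the 12 membrane-spanning 4A genes and 4 of the 8 lymphocyte antigen 6 genes, among them Ly6c1, Ly6c2 and Ly6g. The results of these 2 families therefore overlap with those reported above. In other families only some members changed. Of 46 tripartite motif genes 14 rose and 6 fell (median 0.26, or -0.01 against control 3, camera adjusted p = 0.11), with Trim30b (2.64 ± 0.24) and Trim34b (2.61 ± 0.21) higher and Trim36 lower (-1.54 ± 0.20). Of 12 poly-ADP-ribose polymerase genes 5 rose (median 0.19 (camera adjusted p = 0.0151, and adjusted p = 0.351 with an estimated correlation), or 0.12 against control 3), and Parp11 (2.36 ± 0.25) and Parp10 (2.12 ± 0.19) led them. The medians of these last 2 families turned sign with spike-in scaling, and that of the tripartite motif genes also against control 3. Whether probes of 1 family member also bind others was not tested.

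Transcripts of connective tissue were bright on controls 1 and 2 only. Over 36 markers of fibroblasts, smooth muscle and fat cells, the lower of controls 1 and 2 exceeded the highest of the other arrays by a median of 6.89, against -0.47 for 13 markers of hepatocytes and neurons. This is consistent with RNA of connective tissue cells in these 2 samples, which sorting for monocytes should remove, but 4 of the 13 (Cyp2e1, Ahsg, Stmn2 and Serpina1a) also exceeded the other arrays by more than 2, so the other RNA was not confined to connective tissue genes. Among the brightest were Tagln (7.29 and 7.31 on controls 1 and 2, -0.65 on control 3), Myl9 (7.05 and 7.19, -5.17), Col1a2 (6.71 and 6.87, -2.25) and Dcn (6.66 and 6.89, -6.62), while Acta2 was high on all arrays. The brighter scans of the 2 arrays are argued against by the excess of 6.94 over the spike-ins, and an IFN-beta sample labelled as control 3 by the antiviral genes, which lay below the lowest IFN-beta array there by a median of 2.60, in 36 of 36. Where the RNA came from, and whether control 3 or controls 1 and 2 stand for the untreated state, stays open.

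Other tissue markers had these median levels on controls 1, 2 and 3. Smooth muscle markers stood at 3.95, 4.17 and -5.21, fat cell markers at 1.66, 1.30 and -5.92, endothelium at 0.63, 0.39 and -3.56, cartilage and bone at -1.74, -1.15 and -4.22, and red cells at -1.19, -0.28 and -6.27, with the globin gene Hba-a1 at 7.06, 6.95 and -0.89. Skeletal muscle markers were at -3.18, -3.19 and -2.99, neuron markers at -3.24, -3.28 and -5.36, epidermis at -4.44, -4.55 and -4.64, and hepatocyte markers at -0.88, -6.45 and -6.59.

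Most neutrophil and basophil markers rose with IFN-beta. A lower share of monocytes in those samples was taken to raise the markers of every other blood cell alike. In fact 13 of 18 neutrophil, 11 of 15 basophil, mast cell and eosinophil and 13 of 51 other markers in 5 lists rose. Medians were 1.85 for the first 2 lists and 0.11 for the others, but the values overlapped (lower quartile of the first 2 lists minus upper quartile of the others -0.20). The comparison cannot decide, because a lower share of monocytes raises only the markers of cells that are present, which may differ by type. A lower share of monocytes therefore stays open as an explanation. Another explanation is thinning of blood cell RNA by the other RNA in controls 1 and 2. The neutrophil median was 1.46 above that of oxidative phosphorylation (lower quartile 0.79 against upper quartile 0.15). This cannot decide on thinning, because the other cells may express oxidative phosphorylation genes too and so keep them level. The neutrophil median against control 3, which lacked the connective tissue transcripts, was 1.04. That argues against thinning as the whole cause, but rests on 1 control array. Whether there were more granulocytes, which sorting for monocytes should remove, or more of these transcripts per cell, was not tested.

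Cholesterol synthesis genes fell with IFN-beta. The difference between the slides is argued against by the median of -0.89 on slide 1 alone, though this rests on a single IFN-beta array. An oxysterol that blocks SREBP2 and activates the nuclear receptor LXR would raise LXR targets. In limma 3 of 11 of these, 9 of them in the earlier lists, fell and none rose (median -0.63 (camera adjusted p = 0.0148, and adjusted p = 0.18 with an estimated correlation), -0.41 without and -0.39 against control 3), but they went both ways (upper quartile 0.15), so this stays open, and Ch25h, which makes such an oxysterol, was at -0.83 ± 0.41 (adjusted p = 0.189). An effect of IFN-beta on SREBP-driven transcription, through such an oxysterol or not, may remain, as a hypothesis that these arrays cannot separate from a change in the cells present; cleaved SREBP2 and these transcripts measured in monocytes sorted again after culture would decide it.

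The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. In limma, 1 of the 10 gave as many changed genes as the real split (3866, highest of the others 0, with 31 to 1883 genes at an unadjusted p under 0.05) and 1 of the 10 as many genes changed at least 2-fold (2272, highest of the others 0). For lists 2 of the 10 did (19, highest of the others 19, from control 1 with IFN-beta 1 and 2 against the rest, which does not follow the slides), and the other splits gave from 6 to 17.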
